A study of Homo sapiens with 9 samples.

How the data were processed

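Polyadenylated RNA of NCI-H1299 cells, an established human non-small cell lung carcinoma line that lacks p53, was sequenced in 9 libraries. Cells received PBS, adenovirus with an empty vector or adenovirus carrying CYB5R3 (3 libraries each), with the virus at a multiplicity of infection of 100 and RNA collected at 24 h, per the labels. The labels number the replicates 1 to 3 in each group and do not state whether they are independent cultures. Libraries were made with a stranded mRNA kit, per the labels' protocols. Reads were trimmed with Trim Galore 0.6.4, aligned to hg38 with STAR 2.7.3a and converted to CPM with edgeR 3.32.0, per the submitters' processing notes. The gene annotation, the counting program and its strand setting are not stated.

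The deposited values were CPM, read counts scaled to a library total of 1000000, of 26475 genes in 9 columns. CPM express each gene relative to all reads of its library, so a gene that takes a large share of the reads lowers the CPM of all others. Every library's values were whole multiples of the CPM of 1 read: 100% of the values above 0 came out whole within a tolerance of 0.01 read. The recovered totals lay between 26692808 and 35123875 reads, and 16188 to 16728 genes per library were above 0. At the lowest total, 1 read was worth 0.0375 CPM. Gene positions came from GENCODE release 29 on GRCh38, in which 24522 of the 26475 symbols (92.6%) matched 1 gene.

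The analysis was laid down before the data were examined. Genes with at least 1 CPM in at least 3 libraries were kept, log2(CPM + 1) was computed, and limma 3.58.1 in R 4.3.3 fitted the 3 groups in 1 model with a mean-variance trend and no covariate. Fold changes are on the log2(CPM + 1) scale, which understates changes of low genes. The 3 comparisons, with two-sided tests, were CYB5R3 against empty vector, empty vector against PBS, and CYB5R3 against PBS. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Adjusted p-values in the results are from this limma model unless another tool is named, and errors of fold changes are standard errors of the model. Levels are means of 3 libraries with the SD.

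The genes named were set by rule. In each comparison these were the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM over the 9 libraries and all 3 libraries of one group above all 3 of the other. Symbols of clones, long noncoding and small RNAs were left out, and symbols ending in P plus digits were left out where annotated as pseudogenes. In addition, 12 fixed genes were named whatever their values. For each list described in CYB5R3 against empty vector or in empty vector against PBS, up to 4 called members with the largest change were named, or the 2 with the highest CPM where none was called. In CYB5R3 against PBS the lists were given as counts without naming members.

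The 49 gene lists were fixed at the same time and covered stress responses, cell death, cell cycle, metabolism, innate immunity, invasion-related genes, redox partners of CYB5R3, markers of other cell types and reference genes. Lists with at least 3 tested members were tested with limma's camera, which asks whether the members moved relative to all other genes. The preset inter-gene correlation of 0.01 was used, with an estimated correlation as the alternative and Benjamini-Hochberg adjustment over the 46 lists tested. Counts of called members are given over all genes and adjusted over the list alone.

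Because CYB5R3 took 11.4% to 11.9% of the reads in its own arm, every comparison was repeated with median-ratio size factors, here called median-ratio scaling, computed on genes above 0 in all libraries. Further alternatives were CYB5R3 left out with the rest rescaled, quantile normalization, pseudocounts of 0.25 and 4, no filter, a filter of 5 CPM, robust variance estimation, only the 2 compared groups in the fit, the replicate number as a block, and each library left out in turn. The recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0. On these reads edgeR called 5447 genes between CYB5R3 and empty vector, 82 between empty vector and PBS, and 5690 between CYB5R3 and PBS.

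The limma fit on the deposited and median-ratio scales, edgeR and DESeq2 were tested on simulated data with known changes for CYB5R3 against empty vector and empty vector against PBS, and camera with the preset correlation on 1 list. The other settings and CYB5R3 against PBS were not tested in this way. In simulated CYB5R3 and empty vector libraries (12390 genes) limma on the deposited scale recovered 86.6% of genes changed 1.5-fold and 100% of those changed 2-fold. It also called 2115 of 12189 unchanged genes (17.4%), whose median log2 fold change was -0.18. With median-ratio scaling 74.6% and 95.5% were recovered and 11 of 12185 unchanged genes were called. Besides CYB5R3, only 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold, as many up as down. Median-ratio scaling assumes that most genes are unchanged, which the simulation met by its construction. It therefore does not give the rate of false calls in the real comparison, where 5519 of 12461 genes were called. In simulated empty vector and PBS libraries (12429 genes) 67.2% of genes changed 1.5-fold and 97.0% of those changed 2-fold were recovered, and 14 of 12230 unchanged genes were called. A list raised 1.5-fold was called by camera and 0 of 45 other lists were. Genes were drawn independently in this simulation, so it could not measure false list calls from genes that move together.

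A scan of sequence words in 3' untranslated regions was added after the group comparisons had been seen. For each of the 16199 words of 7 bases (of 16384 possible) present in at least 50 of 11577 genes with an annotated 3' UTR, a linear model gave the log2 shift of genes holding the word, with 3' UTR length, GC content and the 16 dinucleotide shares as covariates and log2 changes limited to 2 in size. It was written in Python 3.11.15 with numpy 2.4.6. In simulation, 5 words with a shift of -0.03 were put in and all 5 ranked 1, with shifts found between -0.0366 and -0.0267. The real log2 changes were first shuffled over the genes, which removed every other link to sequence. The simulation therefore does not show how often an unrelated word ranks high in the real data. No sample column was left out.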

Results

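The series measured mRNA in 9 libraries of NCI-H1299 cells: 3 treated with PBS, 3 with empty adenovirus and 3 with adenovirus carrying CYB5R3. CYB5R3, NADH-cytochrome b5 reductase 3, is a membrane flavoenzyme that passes electrons from NADH to cytochrome b5. Recovered depth was 35123875, 33375251 and 31285451 reads for PBS replicates 1 to 3, 34015080, 26692808 and 33582731 for empty vector, and 34739393, 29676644 and 29399227 for CYB5R3. In a principal component analysis the first component (74.8% of the variance) separated the CYB5R3 libraries from the other 6, and the second (15.8%) separated empty vector replicate 3 from the other 8. Between libraries of a group, the chi-square per degree of freedom was 55.1 and 60.2 for the pairs with empty vector replicate 3 and 1.75 to 9.29 for the other 7 pairs.

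The delivered gene was read first as a check of the labels. CYB5R3 (ENSG00000100243.20, chromosome 22, 42617840 to 42649568, minus strand, GRCh38) stood at 116555 ± 2276 CPM (SD, n = 3) in the CYB5R3 libraries, 205 ± 24.1 CPM (SD, n = 3) with empty vector and 211 ± 17.1 CPM (SD, n = 3) with PBS. The log2 fold change was 9.15 ± 0.09 (SE) over empty vector (limma, adjusted p = 3.3e-13) and -0.046 ± 0.09 between empty vector and PBS (limma, adjusted p = 0.780). Reads of the insert and of the endogenous gene cannot be separated in gene-level values.

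**Figure D1:**
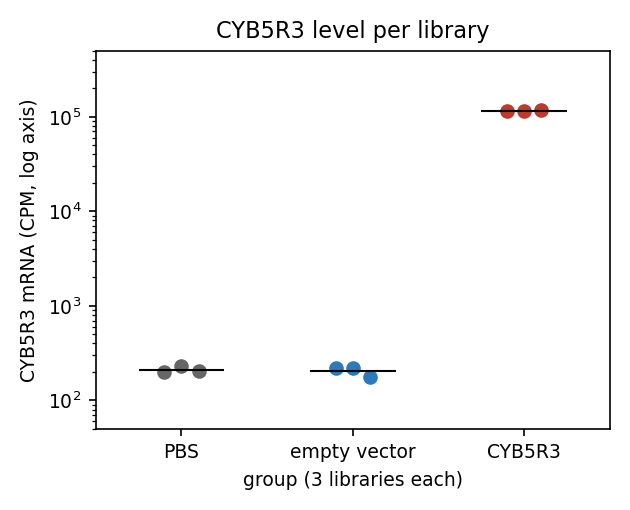
CYB5R3 mRNA in each library (points; CPM on a log axis) by group, with the mean of 3 libraries as a line. The 3 CYB5R3 libraries lie at 114328, 116460 and 118878 CPM and the 6 others between 177 and 230.2 CPM.

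CYB5R3 against empty vector compared the insert at the same stated multiplicity of infection, the question named in the series title. The virus dose that reached the cells was not examined. Heat shock genes and genes of the ATF4 branch of the integrated stress response showed the largest rises. The inducible chaperone HSPA6 went from 0.762 ± 0.178 to 299.6 ± 14.2 CPM (SD, n = 3 each), a log2 fold change of 7.42 ± 0.08 (SE; limma, adjusted p = 8.95e-13). HSPA1A, coding for inducible HSP70, went from 72.6 ± 3.98 to 1809.5 ± 55.3 CPM, and SESN2, a stress-induced inhibitor of mTORC1 signalling, from 22.8 ± 4.37 to 318 ± 11.3 CPM (SD, n = 3 each). Genes of mitosis moved the other way: of 39 tested members of the G2/M and mitosis list, 37 fell and 0 rose, where 7174 of all 12486 tested genes were called lower. The list was called downward (camera, adjusted p = 4.55e-07), but not with an estimated correlation (adjusted p = 0.151 with an estimated correlation).

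Of 16 tested members of the cytosolic heat shock list, 15 rose and 0 fell (15 adjusted over the list alone), with a median log2 fold change of 0.73. HSPA1A rose by 4.62 ± 0.06 (SE), HSPA1B by 4.41 ± 0.06, the HSP70 co-chaperone DNAJB1 by 2.40 ± 0.05 and the co-chaperone BAG3 by 1.82 ± 0.07 on the log2 scale. HSPA1A and HSPA1B have nearly identical sequences, so the split of reads between them is uncertain. HSPA6 lies outside that list (chromosome 1, 161524540 to 161526910, plus strand). Camera called the list (limma, adjusted p = 1.55e-24, and adjusted p = 0.00604 with an estimated correlation).

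Of 30 tested PERK and ATF4 targets, 29 rose and 0 fell (29 adjusted over the list alone), with a median log2 fold change of 0.99 (camera, adjusted p = 1.8e-47, and adjusted p = 0.000299 with an estimated correlation). Besides SESN2 (3.76 ± 0.11, SE), the pseudokinase TRIB3 rose by 2.95 ± 0.06, the cystine transporter SLC7A11 by 2.82 ± 0.15 and the glutathione-degrading enzyme CHAC1 by 2.80 ± 0.08. The transcription factor DDIT3 (CHOP) went from 9.80 ± 0.95 to 51.1 ± 1.77 CPM (SD, n = 3 each), a log2 fold change of 2.27 ± 0.07 (limma, adjusted p = 1.1e-08). ATF4 mRNA rose by 0.22 ± 0.07 (limma, adjusted p = 0.0160), a call that ended without empty vector replicate 1 (adjusted p = 0.0628), empty vector replicate 2 (0.0609) or CYB5R3 replicate 1 (0.0541). DDIT3 overlaps MARS and DNAJB1 overlaps TECR on the opposite strand, and the strand setting of the counting is not stated.

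The ATF6 and XBP1 chaperone list pools targets of the other arms of the endoplasmic reticulum stress response. It had 5 members that rose and 14 that fell of 28 (5 and 14 adjusted over the list alone). The list was not called (camera, adjusted p = 0.266), and after median-ratio scaling it had 8 rises and 4 falls. The chaperone HSPA5 (BiP) rose by 0.28 ± 0.06 on the log2 scale and by 0.59 after median-ratio scaling. XBP1 rose by 1.48 ± 0.07, its activating kinase ERN1 by 1.17 ± 0.26 and HERPUD1 by 0.84 ± 0.06, while the secreted chaperone CRELD2 fell by 0.83 ± 0.10. ERN1 was at 3.04 CPM in empty vector replicate 3 and 8.23 and 8.73 CPM in the other empty vector libraries, and without replicate 3 its log2 fold change was 0.76 (limma, adjusted p = 1.12e-07). Of 20 genes of ER-associated degradation, 0 rose and 15 fell (0 and 15 adjusted over the list alone; camera, adjusted p = 0.414). After median-ratio scaling 4 of these rose and 4 fell. ERLEC1 fell by 0.62 ± 0.08, UBE2G2 by 0.52 ± 0.06, EDEM2 by 0.52 ± 0.06 and OS9 by 0.50 ± 0.06.

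Immediate early genes rose in 27 of 30 tested members, with 0 falls (27 adjusted over the list alone; camera, adjusted p = 1.1e-36, and adjusted p = 0.00519 with an estimated correlation). ATF3 rose by 2.65 ± 0.08, FOSB by 2.57 ± 0.09, EGR1 by 2.04 ± 0.12 and the phosphatase gene DUSP1 by 1.95 ± 0.08. In the NF-kB and inflammatory list 14 of 18 rose and 1 fell (14 and 1 adjusted over the list alone; camera, adjusted p = 4.3e-18, and adjusted p = 0.00519 with an estimated correlation), led by TRAF1 (1.87 ± 0.09), the cytokine LIF (1.43 ± 0.10), BIRC3 (1.22 ± 0.07) and NFKBIZ (1.13 ± 0.09). Interferon-stimulated genes had 4 rises and 15 falls of 26 (4 and 15 adjusted over the list alone; camera, adjusted p = 0.853), with 6 rises and 6 falls after median-ratio scaling. IFIT2 rose by 1.08 ± 0.11, while ISG15 fell by 0.82 ± 0.10, PSMB9 by 0.71 ± 0.12 and USP18 by 0.61 ± 0.11.

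NRF2 targets, genes of the oxidative stress response, had 9 rises and 7 falls of 26 (9 and 6 adjusted over the list alone; camera, adjusted p = 1.8e-07, and adjusted p = 0.00604 with an estimated correlation), and 16 rises and 1 fall after median-ratio scaling. Besides SLC7A11, the haem-degrading enzyme HMOX1 rose by 2.83 ± 0.07, OSGIN1 by 1.5003 ± 0.0719 and thioredoxin reductase TXNRD1 by 1.27 ± 0.08. Ferroptosis regulators had 8 rises and 7 falls of 20 (8 and 7 adjusted over the list alone; camera, adjusted p = 1.2e-05, and adjusted p = 0.0122 with an estimated correlation), and 13 rises and 3 falls after scaling. The list's 3 largest rises, HMOX1, SLC7A11 and CHAC1, also belong to the NRF2 or ATF4 lists, and SAT1 rose by 0.90 ± 0.10. The list of other antioxidant enzymes had 0 rises and 14 falls of 16 (0 and 14 adjusted over the list alone; camera, adjusted p = 0.0840), with 0 rises and 7 falls after median-ratio scaling. TXNRD2 fell by 0.64 ± 0.07, TXN2 by 0.61 ± 0.07, MSRB2 by 0.58 ± 0.11 and GPX4, which reduces lipid peroxides, by 0.57 ± 0.08, with -0.26 after scaling for GPX4.

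Cholesterol synthesis and uptake genes rose in 11 of 24 and fell in 4 (11 and 4 adjusted over the list alone; camera, adjusted p = 4.2e-09, and adjusted p = 0.00519 with an estimated correlation), with 19 rises and 2 falls after median-ratio scaling. HMG-CoA synthase HMGCS1 rose by 1.48 ± 0.06, the sterol oxidase MSMO1 by 0.93 ± 0.07 and INSIG1 by 0.69 ± 0.06, while PMVK fell by 0.77 ± 0.12. Hypoxia (HIF1) targets rose in 11 of 23 and fell in 6 (11 and 7 adjusted over the list alone; camera, adjusted p = 7.4e-09, and adjusted p = 0.00604 with an estimated correlation), with 14 rises and 0 falls after scaling. The members with the largest rise were the mTORC1 inhibitor DDIT4 (2.55 ± 0.08), STC2 (1.77 ± 0.06), EPAS1 (1.51 ± 0.17) and VEGFA (1.37 ± 0.07), of which DDIT4 and STC2 are also in the ATF4 list. Glycolysis genes had 2 rises and 15 falls of 23 (2 and 16 adjusted over the list alone; camera, adjusted p = 0.923), with 6 rises and 2 falls after scaling. SLC16A3 fell by 0.55 ± 0.06, TPI1 by 0.54 ± 0.08, PGAM1 by 0.49 ± 0.05 and LDHA by 0.39 ± 0.06. After scaling TPI1 (-0.23, limma, adjusted p = 0.0582) and LDHA (-0.079, 0.357) were not called.

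The G2/M and mitosis list had 37 falls of 39 (37 adjusted over the list alone), with a median log2 fold change of -0.63 (camera, adjusted p = 4.55e-07, and adjusted p = 0.151 with an estimated correlation). After median-ratio scaling 32 fell and 0 rose. BIRC5 (survivin) fell by 0.94 ± 0.08, the mitotic kinesin KIF20A by 0.87 ± 0.09, GTSE1 by 0.85 ± 0.06 and cyclin B1 (CCNB1) by 0.80 ± 0.07. MKI67, coding for the proliferation marker Ki-67, was at 395 ± 11.7 CPM against 483 ± 180.4 CPM (SD, n = 3 each), -0.21 ± 0.24 (limma, adjusted p = 0.465), and without empty vector replicate 3 its log2 fold change was -0.57 (limma, adjusted p = 3.69e-07). G1/S and DNA replication genes fell in 33 of 42, with 0 rises (34 falls adjusted over the list alone; camera, adjusted p = 0.00669, and adjusted p = 0.0539 with an estimated correlation), or in 14, with 3 rises, after scaling. GINS1 fell by 0.92 ± 0.07, MCM3 by 0.80 ± 0.05, PCNA by 0.74 ± 0.09 and GINS2 by 0.72 ± 0.08.

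The CDK inhibitor CDKN1A (p21) went from 41.2 ± 1.88 to 100 ± 6.16 CPM (SD, n = 3 each), a rise of 1.26 ± 0.07 (limma, adjusted p = 9.3e-07), whereas the CDK inhibitor CDKN2C fell by 1.47 ± 0.07, from 61.7 ± 4.48 to 21.6 ± 0.963 CPM. The p53 target list was called upward (9 rises, 11 falls of 24; 9 and 11 adjusted over the list alone; camera, adjusted p = 0.00584, and adjusted p = 0.0597 with an estimated correlation) although its median was -0.13 and its mean 0.14. After median-ratio scaling it had 11 rises and 6 falls and a median of 0.13, and its call ended (adjusted p = 0.122). Besides SESN2, which is also in the ATF4 list, and CDKN1A, its largest changes were rises of GADD45A (1.40 ± 0.11) and BBC3 (PUMA, 0.90 ± 0.10). NCI-H1299 cells lack p53, so changes of this list cannot be read as p53 activity. Among pro-apoptotic genes 5 rose and 16 fell of 26 (5 and 16 adjusted over the list alone; camera, adjusted p = 0.366), with 10 rises and 8 falls after scaling. Besides BBC3, PMAIP1 (NOXA) rose by 1.26 ± 0.08 and TNFRSF10B by 0.86 ± 0.10. APAF1, the scaffold of the apoptosome, fell by 1.05 ± 0.10 and BAX by 0.69 ± 0.10. Anti-apoptotic genes were called upward (5 rises, 4 falls of 13; 5 and 5 adjusted over the list alone; camera, adjusted p = 0.000316, and adjusted p = 0.151 with an estimated correlation), with 8 rises and 1 fall after scaling, with rises of BAG3, BIRC3 and TNFAIP3 (0.60 ± 0.09) and a fall of BIRC5.

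Nuclear-encoded respiratory chain genes fell in 41 of 42, with 0 rises (41 adjusted over the list alone; camera, adjusted p = 0.000813, and adjusted p = 0.572 with an estimated correlation). After median-ratio scaling 10 fell, 1 rose and the median was -0.21. NDUFA2 fell by 0.80 ± 0.11, SDHC by 0.66 ± 0.07 and NDUFB3 by 0.63 ± 0.13. NDUFB3 was not called after scaling (-0.33, limma, adjusted p = 0.0812). Polyadenylated histone transcripts fell in all 9 tested members (9 adjusted over the list alone; camera, adjusted p = 0.0441, and adjusted p = 0.378 with an estimated correlation), and the call ended without empty vector replicate 3 (adjusted p = 0.142). Of these HIST1H2AC fell by 1.04 ± 0.12, HIST2H2BE by 0.64 ± 0.13, HIST1H2BJ by 0.63 ± 0.10 and HIST3H2A by 0.63 ± 0.11. Cytosolic ribosomal proteins fell in 41 of 48 with 0 rises (42 falls adjusted over the list alone; camera, adjusted p = 0.266), and after scaling 0 fell and 1 rose. RPS10 (-0.56 ± 0.11), RPS15 (-0.47 ± 0.08), RPL13 (-0.41 ± 0.12) and RPL28 (-0.39 ± 0.10) were called lower, but after scaling they were -0.27, -0.16, -0.098 and -0.081 and none was called. RPL13 was at -0.25 without empty vector replicate 3 (limma, adjusted p = 0.000111).

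Of 17 tested members of the list of reductases, cytochromes b5 and partner desaturases and oxidases, CYB5R3 included, 3 rose and 11 fell (3 and 11 adjusted over the list alone; camera, adjusted p = 0.457). After median-ratio scaling 5 rose and 4 fell. The list median with CYB5R3 was -0.25 and the mean 0.33. After CYB5R3, the largest changes were those of MSMO1 (0.93 ± 0.07), CYB5D2 (-0.73 ± 0.10, and -0.51 after scaling) and CYB5RL (-0.62 ± 0.17). CYB5RL was not called after scaling (-0.34, limma, adjusted p = 0.0989) or with quantile normalization (-0.33, 0.0963). CYB5A fell by 0.58 ± 0.07, with -0.28 after median-ratio scaling. The deposited values of CYB5R1 (-0.32 ± 0.07), CYB5R4 (-0.22 ± 0.06) and CYB5B (-0.25 ± 0.05) were called lower, but after scaling they were -0.022, 0.076 and 0.058 and none was called. CYB5R2 did not reach the expression filter.

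Besides CDKN2C, named falls were the MAX partner MXD3 (-1.47 ± 0.10), the helicase PIF1 (-1.43 ± 0.11), B4GAT1, NEURL1B, the Wnt receptor FZD2, ARL6IP1, PBXIP1, GATS, the pseudogene CYP4F35P and PSRC1. MXD3 overlaps RAB24 on the same strand, which makes its value uncertain. GATS had no match in the annotation. These genes stayed lower after median-ratio scaling, at -1.19 to -0.89.

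**Figure D2:**
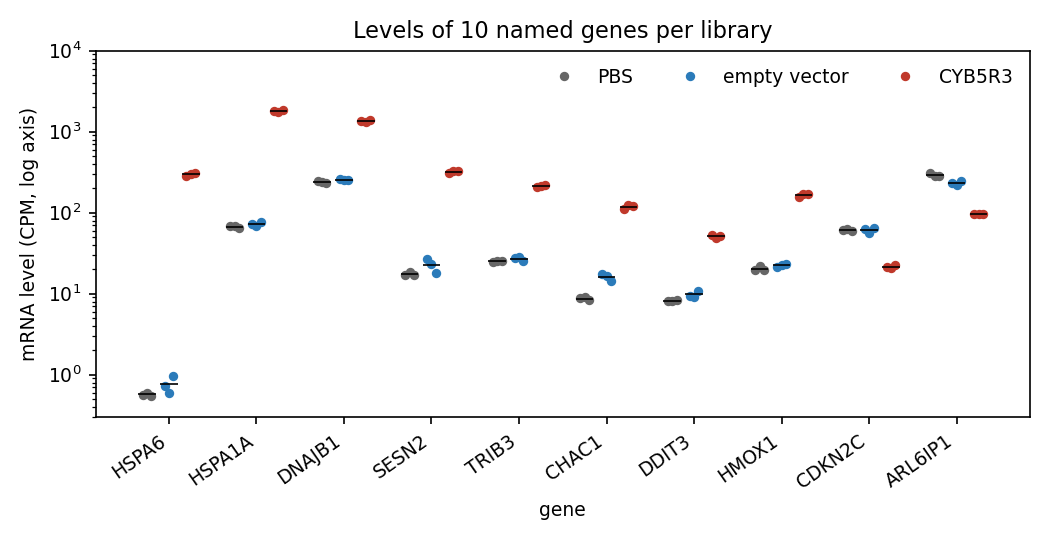
Levels of 10 named genes in each library (points; CPM on a log axis), coloured by group, with the mean of 3 libraries as a line. The 8 stress genes lie higher in the CYB5R3 libraries, as HSPA1A at 1809.5 against 72.6 CPM with empty vector, and CDKN2C and ARL6IP1 lie lower, at 21.6 against 61.7 and 96.2 against 232 CPM.

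Camera called 18 of 46 lists, 14 upward and 4 downward. Of these, 8 held with an estimated correlation, all upward: PERK and ATF4, immediate early, heat shock, NF-kB, cholesterol, HIF1, NRF2 and ferroptosis. The upward calls of the p53 and anti-apoptotic lists, described above, did not hold. The remaining upward calls were TGF-beta targets (7 rises and 7 falls of 19, 7 and 7 adjusted over the list alone; adjusted p = 0.00149, and adjusted p = 0.151 with an estimated correlation), Notch and Wnt targets (4 and 4 of 15, 4 and 4 adjusted over the list alone; adjusted p = 0.00676, and adjusted p = 0.207 with an estimated correlation), YAP targets (4 and 4 of 18, 4 and 4 adjusted over the list alone; adjusted p = 0.0396, and adjusted p = 0.529 with an estimated correlation) and senescence-associated secretory genes (4 and 4 of 8, 4 and 4 adjusted over the list alone; adjusted p = 0.0441, and adjusted p = 0.161 with an estimated correlation). Medians of the TGF-beta, YAP and secretory lists were below 0 (-0.093, -0.063 and -0.051), against a median of -0.29 over all tested genes. Means were 0.088 for TGF-beta targets, -0.033 for YAP targets and 0.13 for secretory genes. The members with the largest changes were BHLHE40 (2.29 ± 0.08), ID1 (-1.03 ± 0.08), SMAD7 (0.93 ± 0.10) and TGIF1 (0.82 ± 0.08) for TGF-beta targets, and HES1 (1.196 ± 0.124), HEY1 (0.70 ± 0.12), NOTCH3 (-0.69 ± 0.18) and JAG1 (0.67 ± 0.09) for Notch and Wnt targets. They were FSTL1 (-0.79 ± 0.05), DLC1 (0.64 ± 0.12), LATS2 (0.53 ± 0.12) and FJX1 (-0.53 ± 0.07) for YAP targets, and VEGFA, CXCL1 (0.84 ± 0.12), TIMP2 (-0.75 ± 0.06) and STC1 (0.67 ± 0.10) for secretory genes. NOTCH3 was not called after median-ratio scaling (-0.43, limma, adjusted p = 0.0607).

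After median-ratio scaling the rises and falls were 8 and 2 for TGF-beta targets, 6 and 3 for Notch and Wnt targets, 8 and 3 for YAP targets and 4 and 1 for secretory genes. Scaling ended 5 of the 18 calls: p53, G1/S, Notch and Wnt, YAP and secretory genes. The YAP call also ended without empty vector replicate 3 (adjusted p = 0.0914), and the secretory call without empty vector replicate 1 (0.0732) or 2 (0.0588). The other 28 lists had adjusted p from 0.0502 to 0.989. Mitochondrially encoded mRNAs were absent from the table, and markers of immune cells (2 members above the filter) and of endothelial cells and fibroblasts (1 member) were too few to test.

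**Figure D3:**
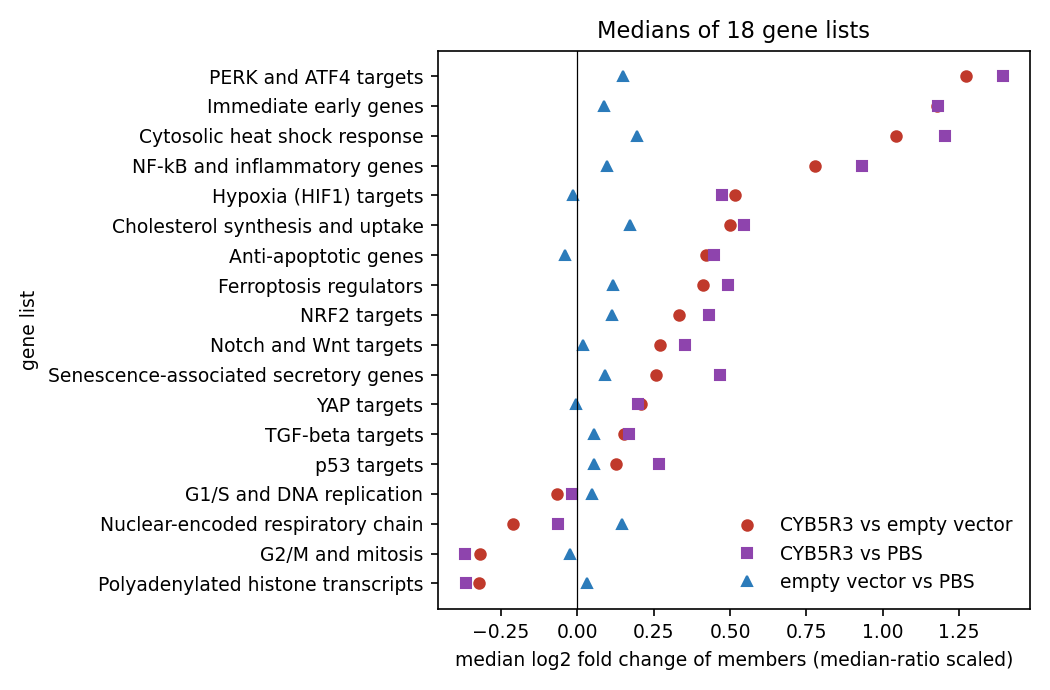
Median log2 fold change of the members of each of 18 gene lists after median-ratio scaling (x axis), in 3 comparisons (symbols). PERK and ATF4 targets lie at 1.27 for CYB5R3 against empty vector and 0.15 for empty vector against PBS; G2/M genes lie at -0.32 and -0.024.

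Over all 12486 genes tested, 8086 were called between CYB5R3 and empty vector, 912 higher and 7174 lower, of which 168 changed at least 2-fold (97 higher, 71 lower). CYB5R3 alone accounted for 11.4% to 11.9% of the reads of its arm, and the deposited CPM of all other genes are relative to a total that includes it. Leaving CYB5R3 out and rescaling the rest gave 1777 higher and 4441 lower, with a median log2 fold change of -0.13. Its share of the reads thus accounts for only part of the downward shift. With median-ratio scaling 5519 of 12461 genes were called, 2967 higher and 2552 lower, and 212 changed at least 2-fold. All 912 genes called higher on the deposited scale were also called higher after scaling, and 2552 of the 7174 called lower stayed called lower. Scaling moved the median log2 fold change upward, from -0.29 to -0.0036. The overlap is largely set by the direction of that shift and is no separate support for the rises. The list of 15 reference genes was not called (camera, adjusted p = 0.923). Its 10 falls (10 adjusted over the list alone), of which 1 was called after scaling, included SDHA, which fell by 0.58 ± 0.06 (-0.27 after scaling), and ACTB, which fell by 0.48 ± 0.06. ACTB was not called after scaling (-0.17, limma, adjusted p = 0.0681).

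**Figure D4:**
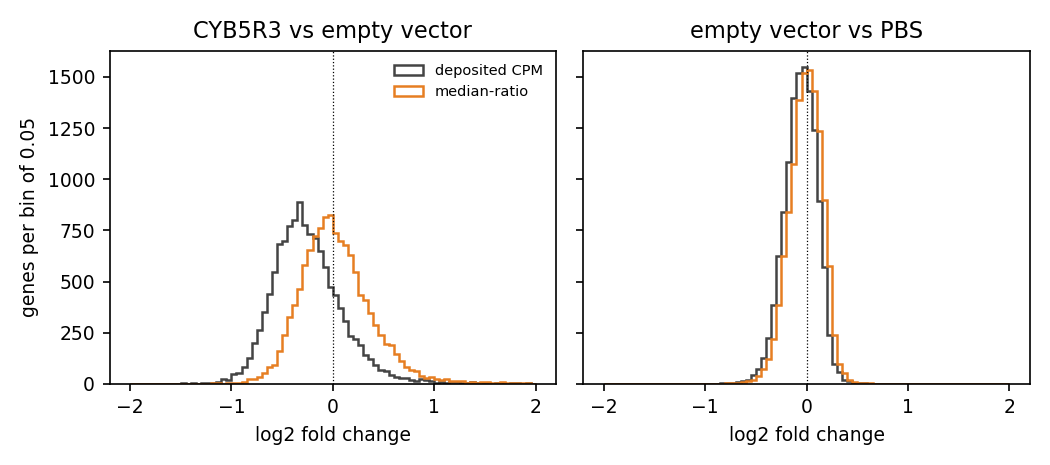
Distribution of log2 fold changes over all tested genes (x axis; genes per bin of 0.05 on the y axis), on the deposited CPM and after median-ratio scaling. For CYB5R3 against empty vector the median is -0.29 on the deposited scale and -0.0036 after scaling; for empty vector against PBS the medians are -0.054 and -0.0035.

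Empty vector against PBS measured the vector without the insert. Only 10 genes rose and 110 fell of 12486 tested, and 1 changed at least 2-fold. CHAC1 had the largest rise among the named genes, from 8.73 ± 0.414 to 16.1 ± 1.61 CPM (SD, n = 3 each; 0.81 ± 0.08, limma, adjusted p = 0.00286), followed by the vasodilator peptide gene ADM (0.60 ± 0.10). APAF1 went from 36.6 ± 2.66 to 19.1 ± 2.78 CPM (-0.91 ± 0.10, limma, adjusted p = 0.0035), and the tumour suppressor RB1 from 78.3 ± 5.59 to 45.6 ± 8.78 CPM (-0.78 ± 0.12, limma, adjusted p = 0.0168). Interferon-stimulated genes did not rise: 0 were called higher and 1, STAT2, lower.

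The other named rises were YRDC (0.45 ± 0.06), HMGCS1 (0.38 ± 0.06), VEGFA (0.37 ± 0.07), ZDHHC18, PHLDA2, CCDC137, ANGPTL4 and DUS1L (0.31 to 0.36). Named falls were KIAA0430, which had the only change of at least 2-fold (-0.95 after median-ratio scaling), DYNLT3 (-0.89 ± 0.08), hexokinase HK2 (-0.81 ± 0.10), DPY19L4 (-0.77 ± 0.07), the Notch effector RBPJ (-0.75 ± 0.08), the transcription factor ETS1 (-0.74 ± 0.08), LANCL1 (-0.70 ± 0.09), CCNG2, KLHL24 and JADE3 (-0.69 to -0.67). The fixed genes were not called: DDIT3 was at 0.23 ± 0.07 (limma, adjusted p = 0.149), ATF4 at 0.24 ± 0.07 (0.120), HSPA5 at 0.11 ± 0.06 (0.367), CDKN1A at 0.10 ± 0.07 (0.437), BAX at 0.088 ± 0.10 (0.614) and MKI67 at -0.35 ± 0.24 (0.421). Of these ATF4 was called without empty vector replicate 3 (0.16, adjusted p = 0.0192) and with DESeq2 (0.30, 0.0280). CYB5R1, CYB5R4, CYB5A and CYB5B lay between -0.035 and 0.051 (adjusted p 0.704 to 0.931).

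Camera called 13 of 46 lists, 11 upward and 2 downward, and 3 upward calls held with an estimated correlation (adjusted p = 0.0303 each). These were ribosome biogenesis and MYC targets (0 of 29 called, 11 higher adjusted over the list alone, median 0.16, with NPM1 at 0.11 and NCL at 0.16; adjusted p = 3.6e-12), PERK and ATF4 targets (1 of 30 called, CHAC1, and 4 higher adjusted over the list alone, median 0.095; adjusted p = 1.9e-06), and cholesterol synthesis and uptake (1 of 24 called, HMGCS1, and 5 higher adjusted over the list alone, median 0.12; adjusted p = 3.2e-06). The heat shock list had 0 of 16 called and 0 adjusted over the list alone (median 0.14; camera, adjusted p = 2.7e-05, and adjusted p = 0.212 with an estimated correlation). Its most abundant members were HSP90AA1, at 7555 ± 661 against 7158 ± 320.3 CPM, and HSP90AB1, at 5650.1 ± 429 against 5025 ± 122 CPM (SD, n = 3 each).

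Further upward calls were cytosolic ribosomal proteins (adjusted p = 1.5e-10, and adjusted p = 0.704 with an estimated correlation), proteasome (1.7e-05, and adjusted p = 0.681 with an estimated correlation), respiratory chain (3.9e-05, and adjusted p = 0.704 with an estimated correlation), the mitochondrial unfolded protein response (0.00446, and adjusted p = 0.196 with an estimated correlation) and immediate early genes (0.00446, and adjusted p = 0.415 with an estimated correlation). These 5 lists had 0 called members over all genes and 0 adjusted over the list alone. Their 2 most abundant members each (RPL4, RPLP0, PSMD2, PSMD8, ATP5B, ATP5A1, HSPD1, HSPA9, FOSL1 and MYC) lay between -0.054 and 0.17 (limma, adjusted p 0.209 to 0.836). Of these FOSL1 was called without empty vector replicate 3 (0.22, adjusted p = 0.00303) and with DESeq2 (0.0186). NRF2 targets (0.00530, and adjusted p = 0.125 with an estimated correlation) had 1 called member, TXNRD1, which fell by 0.51 ± 0.08 (1 adjusted over the list alone) and lost its call without each of the 3 PBS libraries. Ferroptosis regulators (0.0136, and adjusted p = 0.151 with an estimated correlation) had 1 called member, CHAC1 (2 adjusted over the list alone). Without empty vector replicate 3 the calls for ribosomal proteins (adjusted p = 0.286), proteasome (0.416), respiratory chain (0.688, direction turned), mitochondrial unfolded protein response (0.0623), NRF2 targets (0.0623) and ferroptosis (0.0947) ended. The immediate early call ended without empty vector replicate 2 (0.0644).

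Downward calls were interferon-stimulated genes (1 of 26 called, 6 lower adjusted over the list alone, median -0.15; camera, adjusted p = 0.0102, and adjusted p = 0.140 with an estimated correlation) and adenovirus entry receptors (0 of 7 called, 3 lower adjusted over the list alone, median -0.26, with ITGB1 at -0.13 and DSG2 at -0.29; camera, adjusted p = 0.00613, and adjusted p = 0.415 with an estimated correlation). STAT2 fell by 0.44 ± 0.09, a call that ended with median-ratio scaling (adjusted p = 0.0713) and without each library except empty vector replicate 3. The interferon call ended without empty vector replicate 2 (adjusted p = 0.0704). The other 33 lists had adjusted p from 0.0503 to 0.986.

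This comparison was the least stable. The 120 calls became 10, 12 and 11 without PBS replicate 1, 2 or 3, 52 and 67 without empty vector replicate 1 or 2, 54, 50 and 47 without CYB5R3 replicate 1, 2 or 3, and 922 (274 higher, 648 lower) without empty vector replicate 3, among them all 120. Of the named genes, CHAC1, APAF1, DYNLT3, DPY19L4, RBPJ and ETS1 kept their call without each of the 9 libraries in turn; the other 16 lost it without each of the 3 PBS libraries. With median-ratio scaling 73 genes were called, 14 higher and 59 lower, and with the replicate block 36; unadjusted p was below 0.05 for 2376 genes.

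CYB5R3 against PBS combined the vector and the insert. The same stress genes as against empty vector led the rises: HSPA6 went from 0.571 ± 0.028 to 299.6 ± 14.2 CPM (SD, n = 3 each; 7.58 ± 0.08, limma, adjusted p = 7.12e-13), HSPA1A rose by 4.73 ± 0.06 and SESN2 by 4.11 ± 0.11. CHAC1 rose by 3.61 ± 0.08, DDIT3 by 2.51 ± 0.07, CDKN1A by 1.36 ± 0.07 and ATF4 by 0.46 ± 0.07. Named falls included APAF1, from 36.6 ± 2.66 to 8.68 ± 0.221 CPM (-1.96 ± 0.10), LANCL1 (-1.82 ± 0.09) and DYNLT3 (-1.73 ± 0.08).

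Of the 12 named rises 11 were also named against empty vector, the exception being BHLHE40 (2.56 ± 0.08). Named falls also included GATS, the succinic semialdehyde dehydrogenase ALDH5A1, ARL6IP1, PBXIP1, B4GAT1, NEURL1B, the lysosomal cofactor GM2A (-1.63 to -1.51) and KIAA0430. HSPA5 rose by 0.39 ± 0.06 and BAX fell by 0.61 ± 0.10, although BAX was not called after median-ratio scaling (-0.25, limma, adjusted p = 0.0702). MKI67 was at -0.56 ± 0.24 (limma, adjusted p = 0.0566), and was called without empty vector replicate 1 (0.0471), 2 (0.0294) or 3 (5.8e-08) and with only both compared groups in the fit (9.06e-08). CYB5A fell by 0.52 ± 0.07, with -0.17 after scaling (limma, adjusted p = 0.112). CYB5R1 (-0.33 ± 0.07), CYB5R4 (-0.26 ± 0.06) and CYB5B (-0.22 ± 0.05) were called lower on the deposited scale but lay at 0.017, 0.094 and 0.15 after scaling, where only CYB5B of the 3 was called higher (limma, adjusted p = 0.0444).

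Camera called 19 of 46 lists, 16 upward and 3 downward, and 10 upward calls held with an estimated correlation. PERK and ATF4 targets rose in 28 of 30 (29 adjusted over the list alone; adjusted p = 1.5e-54), immediate early genes in 28 of 30 (28 adjusted over the list alone; 1.7e-43), heat shock genes in 15 of 16 (15 adjusted over the list alone; 2.4e-30) and NF-kB genes in 14 of 18 with 1 fall (14 and 1 adjusted over the list alone; 7.7e-21). Cholesterol genes had 12 rises and 2 falls of 24 (12 and 2 adjusted over the list alone; 2.1e-14), NRF2 targets 11 and 5 of 26 (11 and 5 adjusted over the list alone; 5.9e-11), HIF1 targets 9 and 7 of 23 (9 and 7 adjusted over the list alone; 2.9e-09) and ferroptosis regulators 9 and 6 of 20 (9 and 6 adjusted over the list alone; 1.8e-07). Ribosome biogenesis genes had 6 and 3 of 29 (6 and 2 adjusted over the list alone; 1.8e-07). The p53 targets had 8 and 11 of 24 (9 and 11 adjusted over the list alone; 0.00112). After median-ratio scaling the rises and falls were 19 and 1 for cholesterol genes, 17 and 0 for NRF2 targets, 16 and 1 for HIF1 targets, 16 and 2 for ferroptosis regulators, 21 and 0 for ribosome biogenesis genes and 12 and 7 for p53 targets. Scaling ended 7 of the 19 calls: p53 (adjusted p = 0.172), G1/S (0.378), CDK inhibitors (0.279), respiratory chain (0.275), TGF-beta (0.0519), Notch and Wnt (0.255) and YAP (0.0779).

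Lost with an estimated correlation were the downward calls of G2/M genes (38 falls and 0 rises of 39, 39 falls adjusted over the list alone; adjusted p = 2.4e-07, and adjusted p = 0.117 with an estimated correlation), G1/S genes (36 and 1 of 42, 36 and 1 adjusted over the list alone; 0.0360, and adjusted p = 0.0997 with an estimated correlation) and the respiratory chain (40 and 0 of 42, 40 adjusted over the list alone; 0.0445, and adjusted p = 0.746 with an estimated correlation). After scaling 29, 9 and 5 members of these lists fell and 0, 4 and 0 rose. Single libraries ended further calls: the respiratory chain call without PBS replicate 1 (adjusted p = 0.0674) or 2 (0.0708) or without CYB5R3 replicate 1 (0.0563), 2 (0.0830) or 3 (0.0653), the YAP call without PBS replicate 1 (0.0666) or 3 (0.0687), empty vector replicate 3 (0.0537) or CYB5R3 replicate 3 (0.0646), the G1/S call without CYB5R3 replicate 2 (0.0599) and the CDK inhibitor call without PBS replicate 1 (0.0507). The upward calls of anti-apoptotic genes (4 rises and 4 falls of 13, 4 and 4 adjusted over the list alone, and adjusted p = 0.133 with an estimated correlation), TGF-beta targets (8 and 9 of 19, 8 and 9 adjusted over the list alone, and adjusted p = 0.103 with an estimated correlation), Notch and Wnt targets (4 and 6 of 15, 4 and 6 adjusted over the list alone, and adjusted p = 0.133 with an estimated correlation), CDK inhibitors and G1 cyclins (4 and 8 of 17, 4 and 8 adjusted over the list alone, and adjusted p = 0.117 with an estimated correlation), secretory genes (4 and 3 of 8, 4 and 4 adjusted over the list alone, and adjusted p = 0.0790 with an estimated correlation) and YAP targets (4 and 7 of 18, 4 and 7 adjusted over the list alone, and adjusted p = 0.540 with an estimated correlation) were lost too. After scaling the rises and falls of these 6 lists were 6 and 1, 10 and 4, 7 and 3, 9 and 5, 5 and 1, and 6 and 1, in the same order. Although called upward, 4 lists had medians below 0: p53 targets (-0.085, mean 0.12), TGF-beta targets (-0.14, mean 0.059), CDK inhibitors (-0.033, mean -0.045) and YAP targets (-0.11, mean -0.10). The other 27 lists had adjusted p from 0.0640 to 0.999.

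Over all genes 8634 of 12486 were called, 788 higher and 7846 lower, and 380 changed at least 2-fold. The median log2 fold change was -0.33, and with median-ratio scaling 5708 were called, 3020 higher and 2688 lower.

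The virus arms were also set side by side against their shared PBS libraries. Of the 10 genes higher with empty vector, 6 were higher with CYB5R3. Of the 110 lower, 104 were lower with CYB5R3, and 2 genes moved in opposite directions. TXNRD1 was at -0.51 with empty vector and 0.76 with CYB5R3 against PBS. ETS1, lower with empty vector, was at 294, 271 and 273 CPM in the CYB5R3 libraries and 231 to 250 CPM with PBS. APAF1, DYNLT3, LANCL1 and KIAA0430 were named falls in both. Independent lists of these sizes would share 0.631 and 69.1 genes, and 100 simulations of unchanged groups against the same controls shared 0 on average. The simulations hold no effects and the independent lists no shared controls, so neither measures a shared effect. After median-ratio scaling 14 of 14 and 51 of 59 were shared, against 3.39 and 12.7 for independent lists. The 3 PBS libraries enter both lists and are too few to be divided between them, so part of the excess may come from these shared controls.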

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

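The settings reported here were recorded as planned, although the stated reason for median-ratio scaling, the share of reads taken by CYB5R3, came from the data. CYB5R3 itself kept its rise under every setting that gave it a value. When each library was left out, its log2 fold change was 9.05 to 9.20 over empty vector and 9.06 to 9.17 over PBS. It was 9.46 and 9.47 with median-ratio scaling, and 7.25 and 7.21 with quantile normalization. Leaving CYB5R3 out gives no value for it, and edgeR and DESeq2 gave no list tests. For named genes, 4333 values across the settings kept direction and side of the threshold, 199 lost the call, 9 gained one and 19 turned sign. For gene lists the counts were 901, 98, 0 and 1. Depth of 26692808 to 35123875 reads limits genes near 1 CPM, where the filter decides which are tested.

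The pseudocount sets the fold change of low genes by its construction: with 0.25, 356 genes changed at least 2-fold between CYB5R3 and empty vector and 696 between CYB5R3 and PBS. With 4 the counts were 87 and 148, and 0 between empty vector and PBS. Without a filter more genes were tested, and empty vector against PBS gave 75 calls (5 higher, 70 lower), of which 3 and 66 were shared with CYB5R3 against PBS.

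The balance of directions changed with the scaling, and median-ratio and quantile scaling bring it toward even by their construction. With median-ratio scaling CYB5R3 against empty vector gave 2967 genes higher and 2552 lower, empty vector against PBS 73 called (14 higher, 59 lower, 0 changed 2-fold; 2205 at an unadjusted p under 0.05), and CYB5R3 against PBS 5708 (3020 higher, 2688 lower, 243 changed 2-fold), with 14 and 51 calls shared. With CYB5R3 left out, 1777 were higher and 4441 lower against empty vector, and 1499 and 5112 against PBS. Median log2 fold changes were then still -0.13 and -0.17. With quantile normalization, CYB5R3 against empty vector gave 2399 higher and 3063 lower, empty vector against PBS 19 and 69 (0 changed 2-fold), and CYB5R3 against PBS 5425 (2500 higher, 2925 lower, 220 changed 2-fold), with 17 and 60 shared.

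On recovered reads edgeR gave 2871 higher and 2576 lower for CYB5R3 against empty vector (344 changed 2-fold), 82 called for empty vector against PBS (20 higher, 62 lower, 0 changed 2-fold; 2256 at an unadjusted p under 0.05), 5690 for CYB5R3 against PBS (3043 higher, 2647 lower), and 19 and 54 shared calls. DESeq2 gave 2875 higher and 2666 lower (346 changed 2-fold), 408 (170 higher, 238 lower, 0 changed 2-fold), 5733 (2986 higher, 2747 lower), and 147 and 172 shared calls. The cause of the higher DESeq2 count for empty vector against PBS was not tested.

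Empty vector against PBS gave 36 calls with the replicate block (2 higher, 34 lower; 2 and 31 shared) and 12 with only both compared groups in the fit (1 higher, 11 lower, 0 changed 2-fold; 1 and 10 shared), which leaves fewer libraries to estimate the spread. When each library was left out, its calls ranged from 10 to 922, from 1 to 274 higher and from 9 to 648 lower, with 0 to 1 changed 2-fold. Shared calls then ranged from 1 to 134 higher and from 8 to 597 lower. The lowest counts of calls and of shared calls came without PBS replicate 1 and the highest without empty vector replicate 3. The lists called ranged from 8 to 15, and with an estimated correlation 8, 3 and 10 lists were called in the 3 comparisons.

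Left-out libraries gave 7057 to 9504 calls for CYB5R3 against empty vector (724 to 1100 higher, 6329 to 8519 lower, 165 to 212 changed 2-fold) and 7662 to 10155 for CYB5R3 against PBS (630 to 1150 higher, 7004 to 9005 lower, 357 to 412 changed 2-fold). The lists called ranged from 17 to 21 and from 16 to 19.

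Signs turned for 3 fixed genes under scalings that remove the median shift. CYB5R4 was at 0.076 (median-ratio), 0.018 (quantile), 0.077 (edgeR) and 0.069 (DESeq2) against empty vector, and at 0.094, 0.069, 0.10 and 0.087 against PBS. CYB5B was at 0.058 (median-ratio), 0.056 (edgeR) and 0.048 (DESeq2) against empty vector, and at 0.15, 0.016 (quantile), 0.15 and 0.14 against PBS. CYB5R1 was at 0.017, 0.0077 (quantile), 0.020 and 0.0065 against PBS. The respiratory chain list in empty vector against PBS turned downward without empty vector replicate 3, and its adjusted p with each library left out ran from 9.6e-09 to 0.688 (camera); the cause was not tested.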

Other observations

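The tests of virus, library scaling, admixed RNA, base composition and single-library origin below were chosen after the results were seen, as were the scan of sequence words and the small RNA test, which uses a word picked by that scan. For the trend, unrelated insert and split tests the predictions were written before the values of these tests were seen. The trend and unrelated insert tests still address patterns already seen in the data. In CYB5R3 against empty vector, autophagy and lysosome genes had 5 rises and 24 falls of 33 (5 and 24 adjusted over the list alone; camera, adjusted p = 0.873), with 8 and 10 after median-ratio scaling. SQSTM1 (p62), an autophagy receptor, rose by 1.08 ± 0.05 on the log2 scale and the cholesterol transporter NPC1 by 0.79 ± 0.11, while GABARAPL2 fell by 0.89 ± 0.12 and GABARAP by 0.70 ± 0.09. Fatty acid synthesis, desaturation and elongation genes had 6 rises and 11 falls of 25 (6 and 11 adjusted over the list alone; camera, adjusted p = 0.0502), or 12 and 3 after scaling. Fatty acid synthase FASN rose by 0.87 ± 0.17, while ACACB fell by 0.74 ± 0.15, SCD5 by 0.61 ± 0.06 and ELOVL4 by 0.60 ± 0.09. DNA damage repair genes had 0 rises and 15 falls of 25 (0 and 15 adjusted over the list alone; camera, adjusted p = 0.379), or 4 and 3 after scaling. H2AFX fell by 1.00 ± 0.07, RAD51AP1 by 0.91 ± 0.07, CHEK2 by 0.56 ± 0.09 and BRCA1 by 0.49 ± 0.11, which was not called after scaling (-0.19, limma, adjusted p = 0.145).

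Genes of epithelial-mesenchymal transition had 4 rises and 6 falls of 21 (4 and 5 adjusted over the list alone; camera, adjusted p = 0.0550), or 8 and 3 after median-ratio scaling. ZEB2 rose by 0.60 ± 0.13, while TWIST2 fell by 0.57 ± 0.08, S100A4 by 0.52 ± 0.10 and TWIST1 by 0.52 ± 0.10. S100A4 (-0.27, limma, adjusted p = 0.0775) and TWIST1 (-0.22, 0.0724) were not called with quantile normalization, nor TWIST1 with DESeq2 (-0.32, 0.0532). Haem and iron metabolism genes had 0 rises and 16 falls of 19 (0 and 16 adjusted over the list alone; camera, adjusted p = 0.111), or 3 and 5 after scaling. ALAD fell by 0.88 ± 0.08, PPOX by 0.74 ± 0.09, UROD by 0.63 ± 0.09 and CPOX by 0.56 ± 0.06. Among genes holding the AU-rich word TATTTAT in the 3' untranslated region (4206 of 11577 genes), the log2 shift in CYB5R3 against empty vector was 0.0763 ± 0.0079 (SE), the highest ratio of shift to error among 16199 words.

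Heat shock and ATF4 target genes were higher in the CYB5R3 arm. Their median log2 change after median-ratio scaling was 0.154 in empty vector against PBS (upper quartile 0.218) and 1.35 in CYB5R3 against PBS. This argues against the virus alone, provided that both viruses reached the cells at a like dose. The lowest median in CYB5R3 against empty vector over 4 scalings was 0.911 (lower quartile 0.465), which argues against library scaling. The load of any strongly expressed insert stays open and may account for the rise, since 0 groups received virus with an unrelated insert. An action of the CYB5R3 enzyme, a biological explanation, cannot be told apart from that load.

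Empty vector replicate 3 stood apart from the other empty vector libraries. Over 13230 genes the lower chi-square per degree of freedom of its pairs was 60.0 without correction, against at most 10.1 for the other 7 pairs. It was 34.2 after correction for transcript length and 57.2 after correction for GC content, against at most 8.10 and 4.19. With both corrections it was 25.2 against at most 3.45. The trends, mainly that of length, thus account for a large part of the difference but not for the whole. Reads of rRNA and 7S RNA made up 0.00516% of this library and at most 0.00305% of any other, and RNA quality was not tested. Its CYB5R3 level was 41.7 CPM below the lower of the other 2 empty vector libraries (a difference of -41.7), which argues against RNA of the CYB5R3 arm. A difference between cultures or library preparations stays open, and the labels give no batch or date.

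Genes with GTTGTCA in the 3' untranslated region (1317 of 11577) were lower in the virus arms, with a log2 shift in empty vector against PBS of -0.0336 ± 0.0044 (SE) after several rounds of scanning, the lowest ratio of shift to error of 16199 words, with length, GC content and dinucleotide shares in the model. Its ratio of shift to error was -7.68, and CCGTTGT (-7.44) and CGTTGTC (-6.08), which share part of its sequence, were also among the lowest. Unrelated words reached large ratios too, such as ACAGGCG (6.77) and CTCTCTT (-6.08). Without empty vector replicate 3 the ratio of GTTGTCA was -8.27, and the highest ratio of any word was 4.35 (CGCCGTC). The shift of GTTGTCA was -0.0311 without empty vector replicate 3 and -0.0547 ± 0.0116 in CYB5R3 against PBS. No excess of the word was found among genes called lower in CYB5R3 against PBS, on the deposited scale (799 of 7270 against 518 of 4307 others, two-sided Fisher's exact p = 0.0900) or after median-ratio scaling (289 of 2425 against 1028 of 9152, p = 0.350). Its higher share among genes called lower in empty vector against PBS (31 of 106 against 1286 of 11471, or 21 of 58 against 1296 of 11519 after scaling) is no test, since the word was picked on that comparison. The shift was below that of the word in coding sequence by -0.0172 ± 0.0063 in empty vector against PBS, where the coding shift itself was below 0 (-0.0163 ± 0.0048). In CYB5R3 against PBS this difference was -0.0260 ± 0.0180, within 2 errors of 0. A candidate source is a small RNA acting on 3' untranslated regions, such as one cut from the adenoviral VA RNA I; this is a hypothesis, the vector's sequence was not analysed and the labels do not state whether it makes that RNA. Genes are not independent replicates, the shifts are small, and both virus arms against PBS gave an exact permutation p of 0.0119, the smallest that 84 splits allow. The word was picked on these same libraries, so none of these values is an independent test of it.

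For each comparison of 3 against 3 libraries only 10 splits exist, so no share below 0.1 can be reached. The real split gave 8086 genes for CYB5R3 against empty vector, 120 for empty vector against PBS and 8634 for CYB5R3 against PBS, and in each comparison 1 of the 10 splits, the real one, gave as many. The highest of the other splits was 0 in each.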
